A study of Homo sapiens with 9 samples.

How the data were processed

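RNA-seq was performed on HCT116 human colorectal carcinoma cells transfected with a control siRNA or with 1 of 2 siRNAs against ORM1, with 3 libraries per group. Per the labels, the cells were grown in McCoy's 5A medium with bovine serum, transfected with Lipofectamine RNAiMAX, and their RNA was extracted with Trizol and sequenced on an Illumina instrument. The deposited table holds whole-number counts of reads per Ensembl gene identifier for 9 libraries, and per the labels these are raw counts that the authors did not normalise. Per the submitters' processing notes the genome build was hg19. The aligner, the counting tool, the annotation, the strand setting and the siRNA sequences are not given in the sources used here. The whole-number values, with totals that differ between libraries, were compatible with counts, although low values favoured multiples of 4, so that a count may not be a single fragment. The depth was 60698684 to 71431723 counts per library, and 26220 of the 61806 identifiers had 0 counts in all libraries. Counts of near-identical genes such as ORM1 and ORM2, of pseudogenes and of overlapping or antisense genes depend on how the counting treated shared reads, which is unknown.

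A current gene record was found for 61757 identifiers, and 58254 were in GENCODE release 29. Of the 61806 identifiers, 19705 had no gene name and were kept under their identifier. GENCODE release 29 is on GRCh38 and was used for names, coordinates of ORM1 and ORM2, transcript sequences and 3' UTRs, since no hg19 annotation was used here. Samples were grouped by their labels. Genes were kept by edgeR's filterByExpr, which left 20932, and scaled by TMM, with factors of 0.985 to 1.014. All 9 libraries entered 1 quasi-likelihood model in edgeR 4.0.16 (R 4.3.3) with a term for each group, a common biological coefficient of variation of 0.147 and a prior df of 5.8. The contrasts were each ORM1 siRNA against control, the mean of both siRNAs against control, and siRNA 1 against siRNA 2. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are TMM-scaled counts per 1000000 (CPM), and ± gives the SD over 3 libraries. The standard error (SE) of a log2 change is its size over the square root of the test's F statistic. It is approximate, above all where libraries are at 0. ORM1 and ORM2 levels were also compared by exact two-sided permutation tests in scipy 1.17.1. Other computations used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

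The contrasts, tests, thresholds, 36 gene lists and the rule for naming genes were fixed before the data were examined. The lists held 1030 symbols, of which 1018 were matched in the table, and were compared with all other tested genes by camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists of a contrast. The named genes were ORM1 and ORM2, and the 12 largest rises and 12 largest falls in the mean of the siRNAs, among genes called with the same sign under both and with a mean of at least 5 CPM in their higher group. Genes without an official symbol and readthrough genes of 2 symbols were not named. For each siRNA they were also the 5 largest rises and falls called against control and between the siRNAs but not called under the other siRNA, and for each list up to 4 called members with the largest change. Genes outside this rule are said to be chosen after their values were seen. Not all genes that met the rule are given in the text, and the results of some are not reported here.

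The overlap of both siRNAs was set beside that of independent lists and beside 20 simulations of 3 unchanged groups, drawn from the control means, with a shared simulated control. Each comparison was repeated over other splits of the libraries. In 11923 genes with a 3' UTR of at least 50 bases and a mean of at least 2 CPM, every 7-base word was tested for association with the log2 changes, with 100 shuffles of the changes. Alternatives were DESeq2 1.42.0, limma-voom, other scaling and count filters, a fit of only the groups compared, a 2-fold threshold, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. The gene test was checked on simulated counts for siRNA 1 against control with 200 of 20932 genes changed. It recovered 40%, 60%, 88% and 94% of 50 genes each at folds of 1.25, 1.5, 2 and 3, with 6 false among 147 calls. With a log2 drop of 0.15 planted in shuffled changes, the word search ranked 20 of 20 planted words first over 11923 genes. Smaller drops were not tried. On simulated counts with a planted log2 change of 0.2 up or down, camera called 2 of 2 planted lists and 0 of 34 others. The simulated genes were drawn independently, so the effect of correlation within lists was not checked.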

Results

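RNA-seq gene counts were analysed for 9 libraries of HCT116, an established human colorectal carcinoma cell line. The cells had been transfected, with a lipid reagent, with a control siRNA or with 1 of 2 siRNAs against ORM1, and each of the 3 groups held 3 libraries. ORM1 encodes orosomucoid 1, also called alpha-1-acid glycoprotein 1, an acute-phase plasma protein made mainly by the liver. The question addressed was how gene expression in HCT116 cells differed after knockdown of ORM1, and the pair of siRNAs against the same target separates changes seen with both from changes seen with 1. The control libraries held 65141295, 61984423 and 65837173 counts. The siRNA 1 libraries held 60698684, 69847444 and 67885703, and the siRNA 2 libraries 66475531, 67807655 and 71431723. Mitochondrially encoded genes took 8.02% to 8.62% of the counts of a library. The first principal component of log2 CPM (counts per 1000000 of the library) held 36.8% of the variance and separated the control libraries from the libraries of both ORM1 siRNAs, and the second held 18.7% and separated siRNA 1 from siRNA 2. The labels give all libraries the batch value Day 3 and do not say that replicates came from separate cultures. The p-values thus measure only the spread between these libraries, which may be technical.

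ORM1 was lower in every library of both ORM1 siRNAs than in any control library. The gene (ENSG00000229314) lies on the plus strand of chromosome 9, at 114323056 to 114326475 of GRCh38 by its GENCODE 29 record. Its counts were 63, 56 and 59 in the control libraries, 0, 0 and 5 under siRNA 1, and 8, 0 and 12 under siRNA 2. The mean level was 0.915 ± 0.034 CPM (SD, n = 3) in control, 0.025 ± 0.043 CPM under siRNA 1 and 0.097 ± 0.088 CPM under siRNA 2, or 2.7% and 10.6% of control. A count of 0 allows up to 3 counts, which was 0.043 to 0.0494 CPM in the libraries concerned, and this limit covers counting error only and would be higher where a fragment was counted several times. An exact two-sided permutation test gave p = 0.1 for each siRNA, the smallest p that 3 against 3 libraries allow, and p = 0.0238 for both siRNAs together against control. In the model over all genes the log2 change was −5.09 (SE 1.06) under siRNA 1, with an adjusted p of 0.0029, and −3.20 (SE 0.90) under siRNA 2, with an adjusted p of 0.019. Low values of this table favoured multiples of 4, with 11894 values of 4 against 6787 of 3 and 4317 of 5. Over values of 1 to 40, 28% were multiples of 4 and 20.8% had a remainder of 3, although values became rarer with size. The counts of a low gene such as ORM1 may thus rest on fewer sequenced fragments than they state. The difference between the siRNAs did not pass the test, at −1.89 (SE 1.15) and an adjusted p of 0.32.

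**Figure D1:**
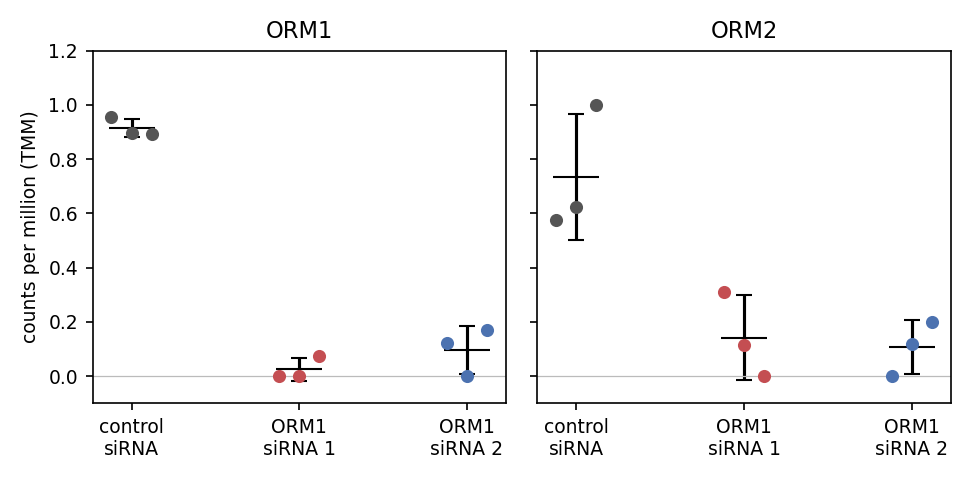
Level of ORM1 and of ORM2 in each library, in TMM-scaled CPM, by group; points are the 3 libraries of a group, and the bars give the mean and 1 SD. ORM1 fell from 0.915 CPM in control to 0.025 CPM under siRNA 1 and 0.097 CPM under siRNA 2, and the ORM2 means were 0.733, 0.141 and 0.106 CPM in the same order.

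ORM2 (ENSG00000228278; GRCh38 chromosome 9, 114329869 to 114333252), which encodes the second form of the same glycoprotein, begins 3393 bp downstream of ORM1. Its counts were 38, 39 and 66 in control, 19, 8 and 0 under siRNA 1, and 0, 8 and 14 under siRNA 2. The mean level was 0.733 ± 0.232 CPM in control, 0.141 ± 0.157 CPM under siRNA 1 and 0.106 ± 0.1 CPM under siRNA 2. The siRNA means were 19.3% and 14.5% of control, with an exact two-sided permutation p of 0.1 for each siRNA and 0.0238 for both together. ORM2 passed the model's test for the mean of the siRNAs, at −2.57 (SE 0.80) and an adjusted p of 0.027, and not for siRNA 1 (adjusted p = 0.094) or siRNA 2 (adjusted p = 0.066) alone. Of the 31-base words of the ORM1 transcript, 56.1% also occur in the ORM2 transcript, so the division of counts between the genes is uncertain. ORM1 was a low gene in these cells, with 28.9% of the 20932 tested genes below it in control. The ORM1 call for siRNA 2 was lost without siRNA 2 replicate 1 and without control replicate 1, 2 or 3, with adjusted p-values of 0.05, 0.057, 0.055 and 0.054, and the ORM2 call without siRNA 1 replicate 2 and without control replicate 1, 2 or 3, with adjusted p-values of 0.058, 0.054, 0.062 and 0.12. The ORM2 change was −3.19 without siRNA 1 replicate 1, and the ORM1 change under siRNA 2 was −3.88 without siRNA 2 replicate 3. Without siRNA 1 replicate 3 both remaining siRNA 1 libraries were at 0 ORM1 counts, and no fold is given for that case.

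The largest rises shared by both siRNAs included regulators of epithelial and progenitor cells and secreted or receptor proteins. Levels are means ± SD over 3 libraries per group, for control and then for siRNA 1 and siRNA 2. TNFSF18, the ligand of GITR, a receptor of T cells, rose from 0.583 ± 0.17 CPM to 6.43 ± 0.30 and 3.99 ± 0.35 CPM. DHRS2, a short-chain dehydrogenase/reductase, rose from 13.5 ± 0.092 CPM to 87.5 ± 2.1 and 36.0 ± 2.6 CPM. EHF, an ETS transcription factor of epithelial cells, rose from 31.7 ± 1.7 CPM to 114 ± 3.7 and 94.3 ± 2.1 CPM, with log2 changes of 1.85 (SE 0.04) and 1.57 (SE 0.04). SOX4, a transcription factor of progenitor cells, rose from 72.9 ± 2.8 CPM to 263 ± 4.5 and 112 ± 0.37 CPM. MYB, another transcription factor of progenitor cells, rose from 3.21 ± 0.64 CPM to 9.49 ± 1.5 and 6.58 ± 0.37 CPM. ADAMTS14, a protease that trims procollagen, rose from 30.0 ± 1.4 CPM to 98.6 ± 4.0 and 55.5 ± 1.2 CPM. IGFBP3, a binding protein of insulin-like growth factors, rose from 6.17 ± 1.3 CPM to 14.5 ± 1.4 and 15.8 ± 0.80 CPM. The germ cell gene TEX19 rose from 1.70 ± 0.33 CPM to 12.2 ± 1.0 and 5.50 ± 0.15 CPM. The other genes among the 12 largest rises were VSNL1, a neuronal calcium sensor (log2 changes 1.88 and 1.10), SCG2, a granin of secretory granules (2.08 and 0.86), KISS1R, the kisspeptin receptor (1.68 and 0.84), and OR51B2, an olfactory receptor (1.15 and 1.66).

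The largest shared falls included chemokine, apoptosis and matrix genes. CXCL8, which encodes interleukin 8, fell from 13.8 ± 1.4 CPM to 3.66 ± 0.34 and 3.63 ± 0.58 CPM, with log2 changes of −1.91 (SE 0.14) and −1.92 (SE 0.14). BIRC3, an inhibitor of apoptosis, fell from 27.9 ± 0.96 CPM to 12.1 ± 0.67 and 12.4 ± 0.38 CPM. BMF, a pro-apoptotic member of the BCL2 family, fell from 8.18 ± 0.91 CPM to 4.47 ± 0.13 and 3.00 ± 0.26 CPM. TGM2, a transglutaminase that cross-links proteins, fell from 98.0 ± 2.9 CPM to 37.6 ± 0.55 and 49.8 ± 2.0 CPM. COL12A1, which encodes a chain of collagen XII, fell from 274 ± 10.2 CPM to 104 ± 3.4 and 149 ± 4.5 CPM. NCEH1, a cholesteryl ester hydrolase, fell from 51.2 ± 1.0 CPM to 15.5 ± 2.5 and 30.3 ± 1.3 CPM. ITGAX, the integrin chain CD11c, fell from 12.6 ± 0.46 CPM to 6.02 ± 0.78 and 4.84 ± 0.84 CPM. RPE65, a retinoid isomerase, fell from 11.5 ± 0.30 CPM to 4.69 ± 0.34 and 4.12 ± 0.29 CPM. SLC4A8, a bicarbonate transporter, had log2 changes of −1.74 and −1.27, ADAM32 −1.66 and −1.28, the cytochrome P450 gene CYP4F12 −0.96 and −1.52, and APOLD1 −1.17 and −1.11. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the highest adjusted p of these 24 genes against control was 0.0036 for CYP4F12 under siRNA 1, and no call against control among them was lost when any 1 library was left out.

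**Figure D2:**
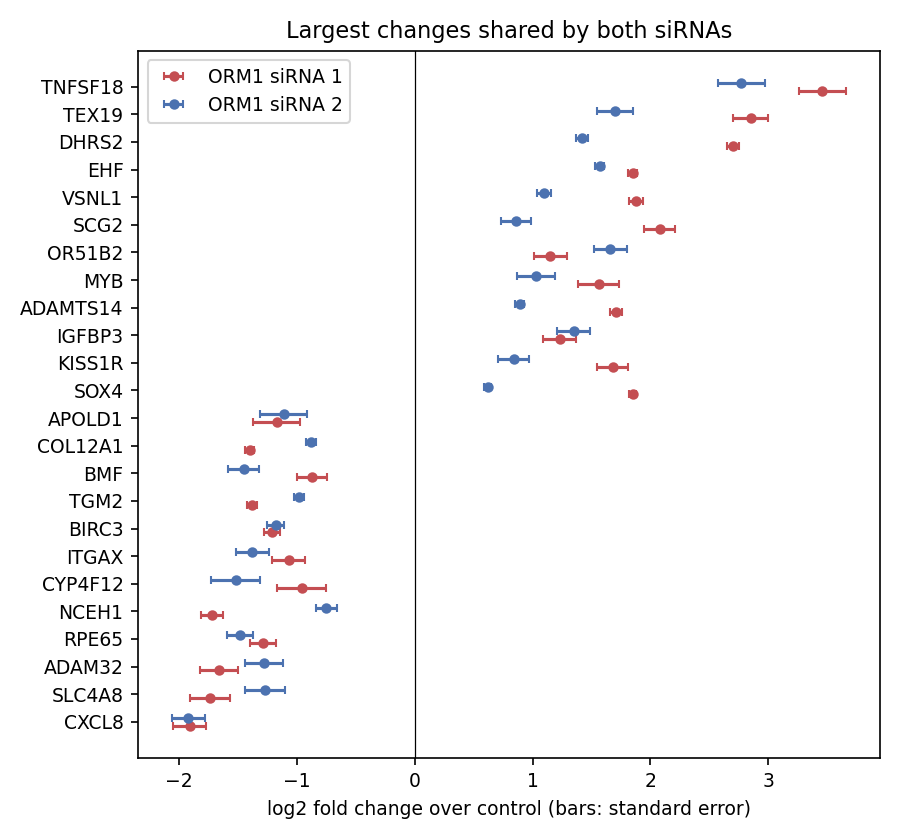
Log2 fold change over control, with its standard error as the bar, of the 12 genes with the largest rise and the 12 with the largest fall shared by both siRNAs, for siRNA 1 (red) and siRNA 2 (blue). The standard errors were derived from the F statistic of the test. The changes run from 3.46 for TNFSF18 under siRNA 1 to −1.92 for CXCL8 under siRNA 2.

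Genes of DNA replication and mitosis rose together. Of the G1/S and DNA replication list, fixed like all 36 lists before the data were examined, 44 of 48 tested members rose and 0 fell (45 and 0 adjusted over the list alone) in the mean of the siRNAs against control. The summed level of this list was 4671 ± 29.2 CPM in control, 5178 ± 3.5 CPM under siRNA 1 and 6226 ± 42.9 CPM under siRNA 2. UNG, which removes uracil from DNA, rose from 70.0 ± 2.8 CPM to 101 ± 3.6 and 109 ± 4.0 CPM. GINS2, a subunit of the replicative helicase, rose from 36.3 ± 0.68 CPM to 45.4 ± 1.9 and 61.1 ± 1.5 CPM. In the G2/M and mitosis list 40 of 50 tested members rose and 0 fell (43 and 0 adjusted over the list alone). Its member CCNB2, a mitotic cyclin, rose from 58.2 ± 3.2 CPM to 84.9 ± 4.2 and 84.6 ± 4.1 CPM. PLK4, a kinase of centriole duplication, rose from 39.1 ± 2.0 CPM to 54.3 ± 4.0 and 59.6 ± 0.56 CPM. Both lists passed limma's camera set test with Benjamini-Hochberg adjustment, at adjusted p = 2.89e-21 and 1.06e-17, and each also passed under either siRNA alone. These values rest on the preset correlation of 0.01 between genes. With an estimated correlation the adjusted camera p-values were far larger, at 0.00231 and 0.0013.

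MYC and its targets in ribosome biogenesis, and WNT targets, were the other lists that were higher by the set test, each called under 1 siRNA alone. The MYC list was not called under siRNA 1 (9 higher and 5 lower of 35, with 9 and 6 adjusted over the list alone), at an adjusted camera p of 0.331, and the WNT list not under siRNA 2 (7 higher and 5 lower of 19, with 7 and 5 adjusted over the list alone), at an adjusted camera p of 0.204. In the mean of the siRNAs, 19 of 35 tested members of the MYC list rose and 2 fell (20 and 2 adjusted over the list alone), with an adjusted camera p of 1.13e-05, and adjusted p = 0.152 with an estimated correlation. NOLC1, a nucleolar phosphoprotein, rose from 288 ± 0.55 CPM to 444 ± 2.0 and 479 ± 4.9 CPM. MYC itself rose from 219 ± 0.93 CPM to 285 ± 4.2 and 326 ± 7.3 CPM. In the WNT target list 11 of 19 tested members rose and 3 fell (11 and 3 adjusted over the list alone), with an adjusted camera p of 0.00155, and adjusted p = 0.0392 with an estimated correlation. The summed level of the WNT list was lower than control under siRNA 2, with 3532 ± 45.9 CPM in control, 3653 ± 17.3 CPM under siRNA 1 and 3018 ± 33.4 CPM under siRNA 2. Besides SOX4, the growth factor BMP4 rose from 75.2 ± 1.7 CPM to 181 ± 2.9 and 119 ± 1.7 CPM and NOTUM, a secreted inhibitor of WNT ligands, rose from 20.8 ± 1.4 CPM to 42.5 ± 0.70 and 26.5 ± 1.1 CPM. CCND1, which encodes the G1 cyclin D1 and is a member of the same list, fell from 1565 ± 17.4 CPM to 778 ± 7.7 and 825 ± 9.0 CPM.

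Targets of p53, NF-kB, YAP and TGF-beta signalling were lower. With an estimated correlation the adjusted camera p-values of these lists were 0.00281, 0.0145, 0.0145 and 0.00579 in that order. The smaller values below rest on the preset correlation. In the p53 target list 2 of 31 tested members rose and 24 fell (2 and 24 adjusted over the list alone), with an adjusted camera p of 9.58e-11. CDKN1A, the cell cycle inhibitor p21, fell from 571 ± 12.4 CPM to 349 ± 13.3 and 317 ± 12.1 CPM. PLK3, a stress-responsive kinase, fell from 80.5 ± 2.7 CPM to 46.9 ± 2.2 and 48.9 ± 1.5 CPM. ZMAT3, an RNA-binding protein, fell from 69.8 ± 4.2 CPM to 40.9 ± 0.61 and 44.2 ± 3.0 CPM. In contrast KITLG, the ligand of the KIT receptor, rose from 728 ± 28.4 CPM to 1416 ± 33.8 and 1299.5 ± 146 CPM. In the NF-kB and TNF list 4 of 23 tested members rose and 13 fell (4 and 14 adjusted over the list alone), with an adjusted camera p of 4.8e-05, and besides CXCL8, the chemokine CXCL2 fell from 1.73 ± 0.31 CPM to 0.471 ± 0.20 and 0.640 ± 0.025 CPM. The summed level of the NF-kB list was higher than control under siRNA 1, with 1102 ± 7.4 CPM in control, 1124 ± 12.6 CPM under siRNA 1 and 1076 ± 8.5 CPM under siRNA 2. In the YAP and TEAD list 0 of 18 tested members rose and 13 fell (0 and 13 adjusted over the list alone), with an adjusted camera p of 1.67e-08. CRIM1, a transmembrane protein, fell from 121 ± 1.4 CPM to 63.1 ± 6.3 and 69.5 ± 0.47 CPM. AMOTL2, an angiomotin family member, fell from 107 ± 3.5 CPM to 74.1 ± 3.7 and 68.8 ± 1.5 CPM. CCN2, the connective tissue growth factor, fell from 14.6 ± 0.62 CPM to 10.7 ± 0.23 and 9.22 ± 0.63 CPM. In the list of TGF-beta, mesenchymal and matrix genes 3 of 31 tested members rose and 19 fell (3 and 19 adjusted over the list alone), with an adjusted camera p of 9.71e-08. Of its members, the matrix protein SPARC and the intermediate filament gene VIM were at 1.65 ± 0.090 and 11.6 ± 0.86 CPM in control, 0.623 ± 0.24 and 6.33 ± 0.81 CPM under siRNA 1, where both fell, and 1.03 ± 0.15 and 10.7 ± 0.57 CPM under siRNA 2, where neither passed the test.

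Lysosomal, sterol, interferon and acute-phase genes were also lower in the mean of the siRNAs. Of these, the cholesterol synthesis and STAT3 lists were not called under siRNA 1, at adjusted camera p-values of 0.189 and 0.294. In the autophagy and lysosome list 4 of 41 tested members rose and 20 fell (5 and 25 adjusted over the list alone), with an adjusted camera p of 2.8e-06, and adjusted p = 0.00717 with an estimated correlation. The sialidase gene NEU1 fell from 46.4 ± 1.4 CPM to 26.2 ± 3.0 and 26.5 ± 1.4 CPM and the protease gene CTSL from 58.1 ± 3.8 CPM to 32.8 ± 0.84 and 43.0 ± 1.5 CPM. GABARAPL1, an ATG8-family gene of autophagosomes, fell from 56.8 ± 2.4 CPM to 37.1 ± 1.8 and 38.4 ± 0.34 CPM. In the cholesterol synthesis list 5 of 26 tested members rose and 16 fell (6 and 16 adjusted over the list alone), with an adjusted camera p of 0.00237, and adjusted p = 0.212 with an estimated correlation. This call was also lost without genes whose 3' UTR held a candidate siRNA seed match, at an adjusted p of 0.0852. MSMO1, a sterol oxidase of this pathway, fell from 99.1 ± 1.5 CPM to 71.4 ± 0.51 and 55.3 ± 1.7 CPM. In the interferon list 1 of 35 tested members rose and 12 fell (1 and 14 adjusted over the list alone), with an adjusted camera p of 0.000529, and adjusted p = 0.0496 with an estimated correlation. Its member IFIT3, a gene induced by interferon, had 1.28 ± 0.15 CPM in control, 0.588 ± 0.14 CPM under siRNA 1 and 0.753 ± 0.28 CPM under siRNA 2, with an adjusted p of 0.014 for the mean of the siRNAs, and of 0.067 without control replicate 3. In the STAT3 and acute-phase list 2 of 17 tested members rose and 6 fell (3 and 6 adjusted over the list alone), with an adjusted camera p of 0.0491, and adjusted p = 0.149 with an estimated correlation. The median log2 change of that list was −0.09 and the test's direction was down, but its mean was above 0, at 0.007. LRG1, a plasma glycoprotein of the acute phase, fell from 1.02 ± 0.14 CPM to 0.218 ± 0.10 and 0.256 ± 0.053 CPM. SERPINA1, or alpha-1 antitrypsin, fell from 9.02 ± 0.52 CPM to 5.75 ± 0.54 and 6.40 ± 0.33 CPM. SERPINA3, or alpha-1 antichymotrypsin, was higher, from 0.00505 ± 0.0087 CPM, below the counting limit, to 0.329 ± 0.27 and 0.120 ± 0.092 CPM. It passed the test under siRNA 1 and for the mean of the siRNAs, and not under siRNA 2 alone. Its estimated log2 change was the largest of the list, but this rank is uncertain with a control below that limit. The SERPINA3 call for the mean of the siRNAs (adjusted p = 0.027) was lost without siRNA 1 replicate 1 or 3 or control replicate 1, 2 or 3, at 0.055, 0.06, 0.092, 0.092 and 0.058. It was also lost by limma-voom and with no count filter. The SERPINA3 call under siRNA 1 was lost by limma-voom and without siRNA 1 replicate 1 or 3 or control replicate 1 or 2. Of the 12 lists called for the mean of the siRNAs, 9 also passed with an estimated correlation, and those lost were the MYC, cholesterol and STAT3 lists. The STAT3 call was also lost without control replicate 3, at an adjusted p of 0.056, and without siRNA 1 replicate 2, at 0.0585.

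**Figure D3:**
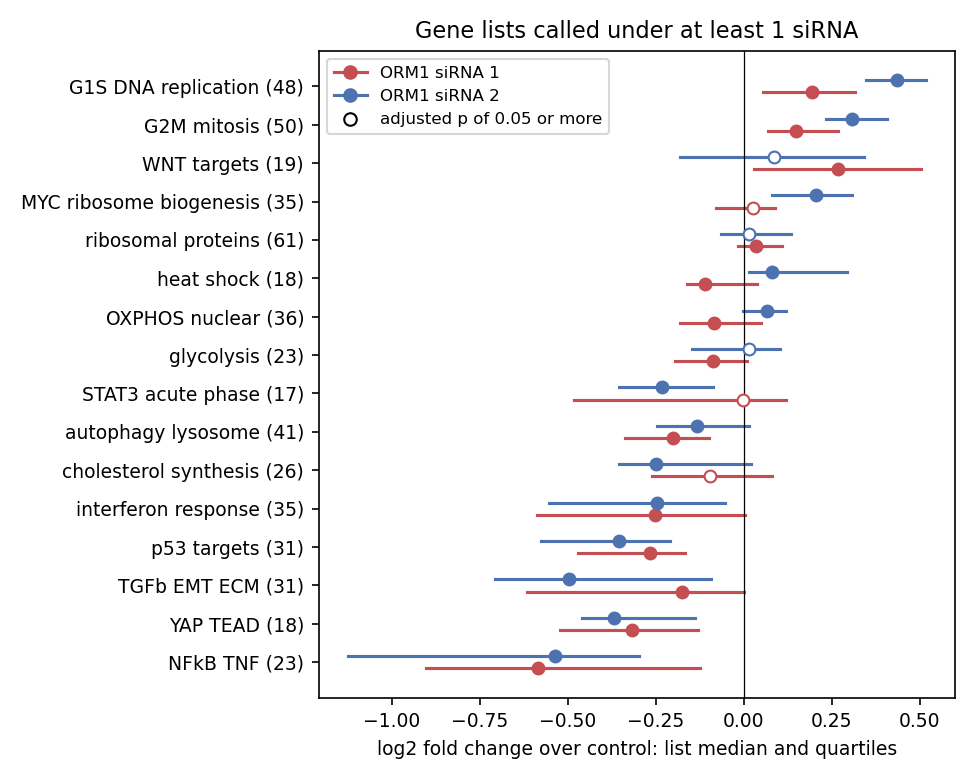
Median log2 fold change over control of the 16 gene lists called under at least 1 siRNA, with bars from the lower to the upper quartile of the members, for siRNA 1 (red) and siRNA 2 (blue), and the number of tested members in parentheses; open symbols mark an adjusted camera p of 0.05 or more. The medians of the G1/S list were 0.19 and 0.43, those of the NF-kB list −0.58 and −0.54, and the heat shock and oxidative phosphorylation lists lay on opposite sides of 0.

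The other 24 lists did not pass the set test for the mean of the siRNAs, although members of most changed in both directions. Of immediate-early and ERK target genes, EGR1, a transcription factor, rose from 107 ± 4.6 CPM to 162 ± 2.9 and 175 ± 4.9 CPM. DUSP5, a phosphatase that inactivates ERK, fell from 289 ± 3.7 CPM to 184 ± 2.9 and 169.6 ± 1.5 CPM. The list had 10 higher and 8 lower of 26 (10 and 8 adjusted over the list alone), at an adjusted p of 0.635. Of epithelial junction and identity genes, ESRP1, a splicing regulator, rose from 99.6 ± 3.5 CPM to 172 ± 4.5 and 158 ± 5.2 CPM. CLDN7, a claudin of tight junctions, rose from 73.1 ± 3.7 CPM to 114 ± 1.5 and 107 ± 4.9 CPM. That list had 13 higher and 8 lower of 28 (13 and 8 adjusted over the list alone), at an adjusted p of 0.307. The glucose transporter gene SLC2A1, in the glycolysis and hypoxia lists, fell from 1149 ± 8.8 CPM to 789 ± 4.3 and 922 ± 14.4 CPM. There were 6 higher and 9 lower of 23 (7 and 9 adjusted over the list alone), at an adjusted p of 0.151, among glycolysis genes. Hypoxia genes had 5 higher and 10 lower of 24 (7 and 11 adjusted over the list alone), at an adjusted p of 0.255. NQO1, a quinone reductase and target of NRF2, rose from 283 ± 7.9 CPM to 336 ± 7.9 and 459 ± 12.2 CPM. HMOX1, or heme oxygenase 1, another such target, fell from 37.4 ± 0.68 CPM to 27.0 ± 1.5 and 24.0 ± 2.2 CPM. The list of NRF2 and ferroptosis genes had 8 higher and 11 lower of 30 (8 and 12 adjusted over the list alone), at an adjusted p of 0.396. DDIT4, an inhibitor of mTOR that ATF4 induces, rose from 272 ± 9.6 CPM to 356 ± 3.8 and 379.8 ± 10.4 CPM. The ATF4 list had 7 higher and 6 lower of 26 (8 and 7 adjusted over the list alone), at an adjusted p of 0.767. The list of the unfolded protein response had 7 higher and 10 lower of 24 (7 and 11 adjusted over the list alone), at an adjusted p of 0.494. AKT and FOXO genes had 8 higher and 7 lower of 23 (8 and 7 adjusted over the list alone), at an adjusted p of 0.919. The BCL2 family and apoptosis list, which includes BIRC3 and BMF, had 10 higher and 13 lower of 33 (11 and 13 adjusted over the list alone), at an adjusted p of 0.424.

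Lipid lists also went both ways. SMPD1, the lysosomal acid sphingomyelinase, changed from 13.0 ± 0.71 CPM to 9.53 ± 1.2 and 8.60 ± 0.37 CPM. SREBF1, which encodes a regulator of fatty acid synthesis, changed from 147 ± 4.7 CPM to 211 ± 4.7 and 181 ± 2.7 CPM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell from 303 ± 11.2 CPM to 181 ± 4.0 and 245 ± 6.9 CPM. Sphingolipid genes had 3 higher and 9 lower of 29 (3 and 9 adjusted over the list alone), at an adjusted p of 0.324. Genes of fatty acid synthesis had 6 higher and 8 lower of 17 (7 and 8 adjusted over the list alone), at an adjusted p of 0.77, and those of fatty acid oxidation 5 higher and 6 lower of 23 (5 and 7 adjusted over the list alone), at an adjusted p of 0.919. Nuclear genes of oxidative phosphorylation had 4 higher and 5 lower of 36 (4 and 5 adjusted over the list alone), at an adjusted p of 0.85. Mitochondrially encoded genes had 3 higher and 2 lower of 15 (3 and 2 adjusted over the list alone), at an adjusted p of 0.919. Heat shock genes had 7 higher and 6 lower of 18 (7 and 6 adjusted over the list alone), at an adjusted p of 0.697. Ribosomal protein genes had 14 higher and 2 lower of 61 (14 and 2 adjusted over the list alone), at an adjusted p of 0.0554. In the housekeeping list there were 7 higher and 2 lower of 21 (7 and 2 adjusted over the list alone), at an adjusted p of 0.269. Genes of the RNA interference machinery had 6 higher and 5 lower of 13 (7 and 5 adjusted over the list alone), at an adjusted p of 0.85. Replication-dependent histone genes, many of which lack a poly(A) tail, had 1 higher and 1 lower of 9 (1 and 1 adjusted over the list alone), at an adjusted p of 0.85. Colonocyte differentiation genes had 1 higher and 1 lower of 10 (1 and 1 adjusted over the list alone), at an adjusted p of 0.885. The median, the mean and the test's direction differed in sign for the uncalled lists of AKT and FOXO, fatty acid oxidation, heat shock and RNA interference genes.

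No list of markers of other cell types passed the set test for the mean of the siRNAs. Hepatocyte markers had 0 higher and 2 lower of 6 (0 and 2 adjusted over the list alone), at an adjusted p of 0.184. Fibroblast markers had 0 higher and 1 lower of 3 (0 and 1 adjusted over the list alone), at an adjusted p of 0.275. Endothelial markers had 0 higher and 1 lower of 6 (0 and 1 adjusted over the list alone), at an adjusted p of 0.51. Leukocyte markers had 0 higher and 1 lower of 9 (0 and 1 adjusted over the list alone), at an adjusted p of 0.885. The summed levels in control, siRNA 1 and siRNA 2 were 13.8 ± 0.067, 9 ± 0.43 and 9.44 ± 0.68 CPM for hepatocyte markers and 60.0 ± 4.5, 52.8 ± 1.2 and 46.9 ± 2.1 CPM for fibroblast markers. They were 16.5 ± 0.27, 18.4 ± 0.73 and 13.4 ± 0.88 CPM for endothelial markers and 21 ± 1.3, 24.3 ± 1.1 and 17.8 ± 2.6 CPM for leukocyte markers. SERPINA1, which also stands in the STAT3 list, gave most of the hepatocyte sum in every group, and the collagen gene COL1A1 most of the fibroblast sum, with 54.1 ± 4.2, 47.9 ± 1.3 and 42.5 ± 1.8 CPM.

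Over all 20932 tested genes, 3387 rose and 3208 fell in the mean of the siRNAs against control, with a median absolute log2 change of 0.288 among the genes called, and 159 and 204 of them changed at least 2-fold. Both siRNAs called 1918 genes higher and 1761 lower than control, 3679 in all, and 135 genes in opposite directions, so 96.5% of the 3814 genes called by both went the same way. Independent lists of these sizes would share 466 genes higher and 390 lower. Because both comparisons used the same controls, all 9 libraries were simulated anew from the control means, without a change between groups. In 20 simulations 0 genes were shared by edgeR's test at the same adjusted threshold. That 0 was all but fixed in advance, since the adjustment leaves almost no calls where no gene is changed. It is therefore no measure of the overlap to be had from shared controls. The simulations held only the spread between libraries, which may be technical. At an unadjusted p below 0.05, 4937 genes had the same sign in both comparisons, against a mean of 212 and at most 236 in the simulations. Across the 11778 genes with a mean of at least 5 CPM, which are not independent replicates, the log2 changes of the siRNAs had a Pearson correlation of 0.671, against 0.502 in the simulations, and a covariance of 0.0615, against 0.0098. The 3 control libraries were not split, as the smaller part would hold a single library, so part of the excess overlap may come from the shared controls.

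**Figure D4:**
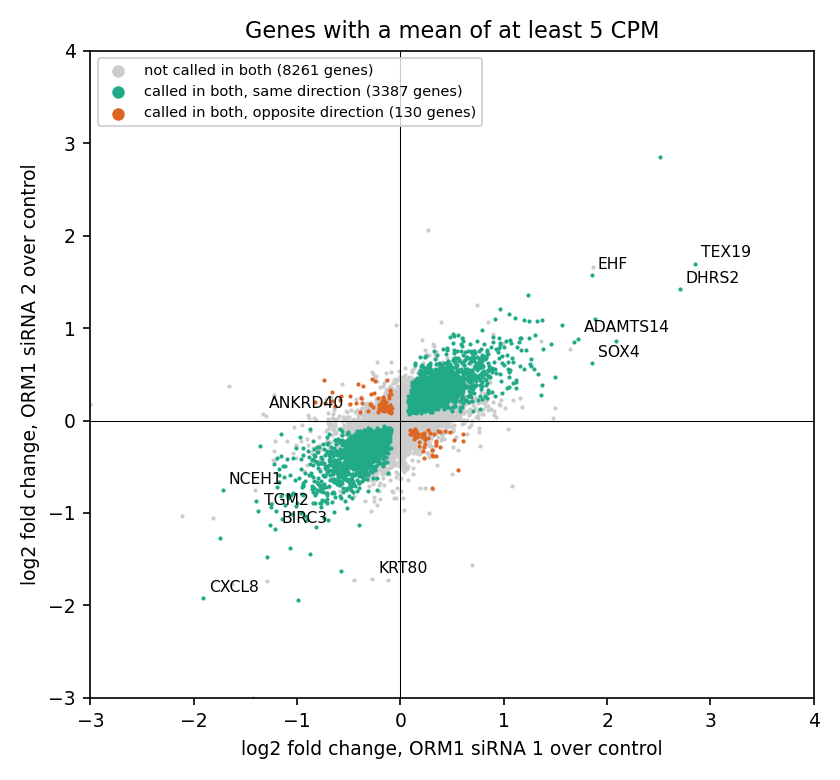
Log2 fold change over control under siRNA 1 (horizontal axis) and siRNA 2 (vertical axis) of the 11778 genes with a mean of at least 5 CPM, each point 1 gene, with 2 genes outside the axes. Green points are the 3387 genes called in the same direction by both siRNAs, orange points the 130 called in opposite directions, and grey points all others.

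Under siRNA 1 alone, the genes with the largest changes that siRNA 2 did not call, and that differed between the siRNAs, included an ankyrin repeat gene, a drug transporter and a collagen. ANKRD40 fell from 116 ± 7.5 to 46.2 ± 2.7 CPM, against 122 ± 0.21 CPM under siRNA 2. SLC35A4, a member of the nucleotide sugar transporter family, fell from 51.2 ± 2.1 to 25.2 ± 0.77 CPM, against 48.8 ± 1.2 CPM under siRNA 2. ABCB1, the drug efflux pump P-glycoprotein, fell from 8.76 ± 0.69 to 4.10 ± 0.73 CPM, against 7.53 ± 1.0 CPM under siRNA 2. KYAT1, a kynurenine aminotransferase, and GLT8D2 had log2 changes of −1.30 and −1.23 under siRNA 1. The 3' UTRs of ANKRD40 and GLT8D2 hold the 7-mer CTATAAC, which also occurs in the ORM1 transcript, as do those of NCEH1 and BIRC3 among the largest shared falls and of VSNL1 among the largest shared rises. Among members of the lists named, NDUFA4 and HSPD1 also hold it. COL17A1, a collagen of hemidesmosomes, rose from 2.03 ± 0.42 to 7.28 ± 0.22 CPM, against 1.94 ± 0.40 CPM under siRNA 2. PROM2, a pentaspan membrane protein, rose from 1.74 ± 0.17 to 5.55 ± 0.50 CPM, against 2.12 ± 0.46 CPM under siRNA 2. YPEL1 rose from 1.56 ± 0.57 to 5.88 ± 0.62 CPM, against 2.39 ± 0.26 CPM under siRNA 2. The pseudogene TCAM1P rose from 1.86 ± 0.52 to 5.6 ± 1.1 CPM, against 2.96 ± 1.1 CPM under siRNA 2, and as a pseudogene is uncertain. Its difference between the siRNAs (adjusted p = 0.041) was lost without siRNA 1 replicate 1 or 3, siRNA 2 replicate 2 or 3 or control replicate 3, with adjusted p-values of 0.13, 0.11, 0.097, 0.12 and 0.057. The replicate block and the fit with no count filter ended that call too. Against control, 3281 genes rose and 3108 fell under siRNA 1, and 290 and 237 of them changed at least 2-fold.

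By camera, 13 lists were called under siRNA 1. The p53, NF-kB, YAP, TGF-beta, autophagy and interferon lists were lower. Targets of p53 had 3 higher and 21 lower of 31, with 3 and 22 adjusted over the list alone. The NF-kB list had 3 higher and 12 lower of 23, with 4 and 14 adjusted over the list alone. The YAP list had 0 higher and 12 lower of 18, with 1 and 13 adjusted over the list alone. TGF-beta and matrix genes had 3 higher and 15 lower of 31, with 3 and 15 adjusted over the list alone. The autophagy list had 4 higher and 21 lower of 41, with 4 and 24 adjusted over the list alone. Interferon genes had 0 higher and 13 lower of 35, with 0 and 13 adjusted over the list alone. The interferon list had an adjusted camera p of 0.00252, and adjusted p = 0.0749 with an estimated correlation. The G1/S, G2/M and WNT target lists were higher. G1/S genes had 28 higher and 4 lower of 48, with 31 and 4 adjusted over the list alone. G2/M genes had 30 higher and 3 lower of 50, with 32 and 4 adjusted over the list alone. WNT targets had 11 higher and 2 lower of 19, with 11 and 2 adjusted over the list alone. The glycolysis list was lower (4 higher and 11 lower of 23, with 4 and 12 adjusted over the list alone), at an adjusted camera p of 0.00766, and adjusted p = 0.486 with an estimated correlation. The heat shock list was lower (2 higher and 12 lower of 18, with 2 and 12 adjusted over the list alone), at an adjusted camera p of 0.0149, and adjusted p = 0.42 with an estimated correlation. The oxidative phosphorylation list was lower (3 higher and 13 lower of 36, with 3 and 13 adjusted over the list alone), at an adjusted camera p of 0.0363, and adjusted p = 0.723 with an estimated correlation. The ribosomal protein list was higher (13 higher and 1 lower of 61, with 12 and 1 adjusted over the list alone), at an adjusted camera p of 0.0354, and adjusted p = 0.815 with an estimated correlation. The summed level of the heat shock list, 11410 ± 74.4 CPM in control, was higher under siRNA 1, at 11600 ± 23.4 CPM. NDUFA4, a subunit of the respiratory chain, fell from 52.4 ± 3.8 to 32.2 ± 0.42 CPM, against 49.2 ± 3.1 CPM under siRNA 2. The oxidative phosphorylation call was lost without control replicate 2 or 3 or siRNA 1 replicate 1, at adjusted p-values of 0.1, 0.136 and 0.12, and the ribosomal protein call without control replicate 1 or siRNA 1 replicate 3, at 0.621 and 0.274.

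Under siRNA 2 alone, the largest changes that siRNA 1 did not call, and that differed between the siRNAs, included a keratin, a lipase and a small GTPase. KRT80, an epithelial keratin, fell from 9.39 ± 0.48 to 2.86 ± 0.37 CPM, against 7.76 ± 0.51 CPM under siRNA 1. ACHE, or acetylcholinesterase, fell from 6.5 ± 0.55 to 3.30 ± 0.63 CPM, against 5.33 ± 0.43 CPM under siRNA 1. LIPG, or endothelial lipase, fell from 9.80 ± 1.3 to 5.34 ± 0.69 CPM, against 8.20 ± 0.89 CPM under siRNA 1. DRAXIN, an axon guidance protein, fell from 11.5 ± 0.77 to 6.07 ± 0.23 CPM, against 9.82 ± 0.24 CPM under siRNA 1. RAB26, a GTPase of secretory granules, rose from 13.5 ± 1.0 to 24.8 ± 1.5 CPM, against 15.6 ± 1.2 CPM under siRNA 1. RPL14P1 fell from 38.7 ± 1.2 to 11.7 ± 0.84 CPM, against 35.5 ± 7.4 CPM under siRNA 1. DHFRP1 rose from 11.9 ± 1.8 to 20.2 ± 0.91 CPM, against 14.1 ± 2.2 CPM under siRNA 1. As pseudogenes both may share reads with their parent genes. AGAP2-AS1, an antisense RNA, rose from 1.67 ± 0.67 to 6.46 ± 2.0 CPM, against 1.66 ± 0.82 CPM under siRNA 1, and is uncertain because the use of strand in the counting is not given. COX20, an assembly factor of cytochrome c oxidase, rose from 22.3 ± 6.7 to 46.7 ± 13.0 CPM, against 29.2 ± 4.3 CPM under siRNA 1. LINC00173 rose from 6.65 ± 1.4 to 11.8 ± 1.0 CPM, against 8.27 ± 0.20 CPM under siRNA 1. The differences between the siRNAs of COX20, LINC00173 and DHFRP1 (adjusted p = 0.047, 0.022 and 0.014) depended on single libraries. That of COX20 was lost without siRNA 1 replicate 1, 2 or 3, siRNA 2 replicate 2 or 3 or control replicate 3, at 0.16, 0.069, 0.1, 0.12, 0.19 and 0.055. It was also lost by DESeq2's Wald test, with library size only, with no count filter and without genes holding a motif. That of LINC00173 was lost without siRNA 1 replicate 1, 2 or 3 or siRNA 2 replicate 2 or 3, at 0.053, 0.068, 0.07, 0.052 and 0.082, and that of DHFRP1 without siRNA 1 replicate 3 (0.054) or siRNA 2 replicate 3 (0.05). Against control, 2970 genes rose and 2627 fell under siRNA 2, and 101 and 211 of them changed at least 2-fold.

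The same test called 13 lists under siRNA 2. The G1/S, G2/M, MYC, heat shock and oxidative phosphorylation lists were higher. G1/S genes had 47 higher and 0 lower of 48, with 47 and 0 adjusted over the list alone. G2/M genes had 45 higher and 0 lower of 50, with 47 and 0 adjusted over the list alone. The MYC list had 23 higher and 0 lower of 35, with 24 and 1 adjusted over the list alone. Heat shock genes had 9 higher and 2 lower of 18, with 10 and 4 adjusted over the list alone. Oxidative phosphorylation genes had 6 higher and 0 lower of 36, with 5 and 0 adjusted over the list alone. The heat shock call had adjusted p = 0.000602, and adjusted p = 0.182 with an estimated correlation, and the oxidative phosphorylation call 0.0391, and adjusted p = 0.729 with an estimated correlation. HSPD1, the mitochondrial chaperonin HSP60 and a member of the heat shock and MYC lists, rose from 1069.9 ± 20.6 to 1546 ± 29.5 CPM, against 1056 ± 8.6 CPM under siRNA 1. The p53, TGF-beta, YAP, NF-kB and autophagy lists were lower. Targets of p53 had 1 higher and 25 lower of 31, with 2 and 25 adjusted over the list alone. TGF-beta and matrix genes had 2 higher and 17 lower of 31, with 2 and 18 adjusted over the list alone. The YAP list had 1 higher and 12 lower of 18, with 1 and 13 adjusted over the list alone. The NF-kB list had 3 higher and 13 lower of 23, with 4 and 14 adjusted over the list alone. The autophagy list had 2 higher and 18 lower of 41, with 2 and 18 adjusted over the list alone. Cholesterol synthesis (3 higher and 17 lower of 26, with 4 and 17 adjusted over the list alone) was lower at adjusted p = 6.1e-06, and adjusted p = 0.0646 with an estimated correlation. Interferon genes had 1 higher and 10 lower of 35, with 1 and 10 adjusted over the list alone. STAT3 and acute-phase genes had 1 higher and 7 lower of 17, with 2 and 7 adjusted over the list alone. Both lists were lower, at adjusted p = 0.000826 and 0.00534, and both had adjusted p = 0.0544 with an estimated correlation. The oxidative phosphorylation call was lost without control replicate 1 or siRNA 2 replicate 2 or 3, at adjusted p-values of 0.256, 0.217 and 0.159.

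Compared with each other, the siRNAs differed in replication, mitosis, heat shock, ribosome biogenesis and WNT target genes, among others. Of the 20932 genes tested, 1694 were higher and 2058 lower under siRNA 1 than under siRNA 2, and 141 and 48 of them differed at least 2-fold. In the G1/S list 36 of 48 members were lower and 1 higher under siRNA 1 (40 and 1 adjusted over the list alone), with a median log2 difference of −0.23 and an adjusted camera p of 5.56e-25. In the heat shock list 17 of 18 were lower (17 adjusted over the list alone), at an adjusted camera p of 2.48e-15. With an estimated correlation the adjusted camera p-values of the G1/S and heat shock lists were 0.00146 and 0.0203. The G2/M, MYC, ATF4 and autophagy lists were also lower under siRNA 1 than under siRNA 2. G2/M genes had 0 higher and 26 lower of 50, with 1 and 34 adjusted over the list alone. The MYC list had 0 higher and 22 lower of 35, with 0 and 24 adjusted over the list alone. ATF4 targets had 1 higher and 11 lower of 26, with 1 and 14 adjusted over the list alone. The autophagy list had 5 higher and 13 lower of 41, with 5 and 13 adjusted over the list alone. The WNT, AKT, TGF-beta, epithelial, cholesterol and apoptosis lists were higher under siRNA 1. WNT targets had 10 higher and 2 lower of 19, with 13 and 2 adjusted over the list alone. AKT and FOXO genes had 10 higher and 0 lower of 23, with 11 and 0 adjusted over the list alone. TGF-beta and matrix genes had 13 higher and 3 lower of 31, with 15 and 4 adjusted over the list alone. Epithelial junction genes had 11 higher and 2 lower of 28, with 12 and 2 adjusted over the list alone. Cholesterol synthesis genes had 10 higher and 1 lower of 26, with 16 and 1 adjusted over the list alone. Apoptosis genes had 9 higher and 1 lower of 33, with 10 and 1 adjusted over the list alone. The largest adjusted camera p of these 12 lists was 0.0118, for autophagy. SOX4 was 1.23 higher under siRNA 1 on the log2 scale (SE 0.03), and HSPD1 was lower, with a difference of −0.55 (SE 0.02).

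Of the 18 lists called between the siRNAs, 12 passed with an estimated correlation, which were those just named. The other 6 were lost. Oxidative phosphorylation (0 higher and 14 lower of 36, with 0 and 17 adjusted over the list alone) had adjusted p = 8.83e-08, and adjusted p = 0.343 with an estimated correlation. For glycolysis (3 higher and 12 lower of 23, with 4 and 13 adjusted over the list alone) and fatty acid oxidation (2 higher and 8 lower of 23, with 3 and 9 adjusted over the list alone) these values were 0.000395 and 0.0204, and adjusted p = 0.331 and 0.376 with an estimated correlation. For p53 targets (10 higher and 1 lower of 31, with 12 and 1 adjusted over the list alone), colonocyte differentiation (4 higher and 1 lower of 10, with 5 and 1 adjusted over the list alone) and housekeeping genes (1 higher and 7 lower of 21, with 2 and 8 adjusted over the list alone) they were 0.0205, 0.0269 and 0.0292, and adjusted p = 0.0688, 0.104 and 0.479 with an estimated correlation. KRT20, a keratin of differentiated colon epithelium, rose from 0.425 ± 0.18 to 2.06 ± 0.29 CPM, against 0.473 ± 0.020 CPM under siRNA 2. Without siRNA 2 replicate 2 the p53, fatty acid oxidation and housekeeping calls were lost, at adjusted p-values of 0.0507, 0.0624 and 0.0507, and the housekeeping call also without siRNA 1 replicate 1 (0.0794) and without siRNA 2 replicate 3 (0.067).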

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

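The shares of genes holding a sequence motif, the tests of the words of the ORM1 transcript under siRNA 2, of lists shared by both siRNAs and of part of the fragments counted about 4 times were chosen after the result was seen. So were the fits without motif genes and with counts divided by 4.

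A set of 135 genes was called in opposite directions by the siRNAs against control, and the difference between the siRNAs was called for each, as this selection all but ensures. Of these, 55 were higher under siRNA 1 and lower under siRNA 2, and 80 the reverse. The heat shock list also moved apart by a test of the difference itself, with medians of −0.11 under siRNA 1 and 0.08 under siRNA 2, and a median difference of −0.173. The list of oxidative phosphorylation had medians of −0.09 and 0.07 and a median difference of −0.127, with adjusted p = 0.343 for that difference with an estimated correlation. After a regression on GC content, length and expression level, which explained 4.5% of the variance of the difference over all genes, these medians were −0.106 for heat shock and −0.073 for oxidative phosphorylation. Other lists called between the siRNAs also shrank, G2/M from −0.150 to −0.093, glycolysis from −0.092 to −0.032, fatty acid oxidation from −0.086 to −0.046 and housekeeping genes from −0.076 to −0.022. The MYC list went from −0.148 to −0.105, ATF4 from −0.185 to −0.122 over the members with a value, and WNT targets from 0.265 to 0.19.

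Genes lower under siRNA 1 than under siRNA 2 held the word CTATAAC in their 3' UTRs more often than the rest, in 231 of 1939 searched genes (11.9%) against 540 of 9984 (5.4%). The word was picked from the same changes, so these shares only describe it. Its association score in the difference between the siRNAs was z = −12.4, the lowest of all words tested, against a range of −5.5 to 5.3 in shuffled data, and against control it was −8.6 under siRNA 1 and −0.3 under siRNA 2. The word lies at positions 351 to 357 of the 802-base ORM1 transcript, in the coding sequence, and also occurs in the ORM2 transcript. Of all words, 4.8% occur in the ORM1 transcript. Seed matches of siRNA 1 are thus a candidate cause for part of these genes. A share of 11.9% argues against direct matches to CTATAAC as the cause of most of them. The overlapping word TATAACA, also in the ORM1 transcript and held by 1503 genes, was associated too (z = −6.9) and was not counted. The 1708 genes without CTATAAC may hold it, and they stay open. For genes lower under siRNA 2, the most associated word (z = 6.4) is not in the ORM1 transcript. The strongest ORM1 word had z = −3.9, inside the shuffled range of down to −4.6, so no siRNA 2 seed was detected. The search was checked only with a planted log2 drop of 0.15. Genes with CTATAAC had a median difference of −0.08, against −0.01 without it, so a weaker siRNA 2 seed stays open.

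Genes higher under both siRNAs than in control held the words CGGAGAA or TCGGAGA in 158 of 1729 searched genes (9.1%) against 556 of 10194 (5.5%), and these words too were picked from the same changes. Of the genes named here, ADAMTS14, NOLC1, COL17A1 and BCL2L11, which rose under 1 siRNA or both, and TGM2, which fell, hold one of them. The first word had z = 6.4 in the mean of the siRNAs, against at most 5.2 in shuffled data, and release from seed matches of the control siRNA is thus a candidate cause for part of these genes. The share of 9.1% argues against direct matches to these words as the cause of most of them. The overlapping word GGAGAAA, held by 3172 genes, was associated too (z = 5.8). It was counted neither in this share nor among the motifs left out of the G1/S list, so matches to it stay open. The median change of the G1/S list, 0.307, was 0.308 without members holding a motif. It was 0.296 after a regression on GC content, length and expression level, which argues against such a trend as its cause. Of the 10 lists called under both siRNAs 8 went the same way, which the shared controls may bring about as well. Loss of ORM1 thus stays open. It cannot be told apart from loss of ORM2, whose mean level was also lower under both siRNAs. Nor can it be told apart from indirect effects of the single control siRNA that both comparisons share.

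Low counts favoured multiples of 4 in the table as a whole. Values of 4 numbered 11894, against 6787 values of 3 and 4317 of 5. Over values of 1 to 40, 28% were multiples of 4, and remainders of 1, 2 and 3 took 26.1%, 25.2% and 20.8%. An even spread would give 25% each, but values became rarer with size, which would place multiples of 4 below that. For each sequenced fragment having been counted about 4 times, the criterion fixed beforehand was a mean replicate variance over mean of at least 3. This criterion was met, as given below, but it cannot tell each fragment from part of them. The 19872 values of 1 or 2, which were not the planned test, argue against each fragment having been counted so. The variance between replicates over their mean averaged 5.01 (median 3.05) in 4858 genes with means of 8 to 40 control counts. Part of the fragments having been counted about 4 times could give this, though other spread between replicates would raise it too. The tests above estimate their spread from the replicates, and division by 4 left the number of called genes within 1.5 times for each comparison (6637 against 6389 for siRNA 1). The tally pooled the libraries of all groups, and no biological explanation was tested.

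Other splits of the libraries gave far fewer calls. The 10 splits of 6 libraries are too few for a share under 0.05, and the real split called 6389 genes for siRNA 1 against control, with 3 in the highest other split, 5597 for siRNA 2, with 1, and 3752 between the siRNAs, with 3. For the mean of the siRNAs against control, a model of 2 groups called 4509 genes in the real split. As large a number came in only 1 of the 84 splits. The highest other split called 1846, and it set an siRNA group apart from control and the other siRNA together. Its calls thus mix the difference of that siRNA from control with its difference from the other siRNA. For the genes shared by both siRNAs the real arrangement gave 3679, the most of 40 arrangements. The others were exchanges of whole groups and random draws. The highest of them gave 2043, and it kept the groups whole and exchanged their roles. Among arrangements that mixed the groups the highest was 608. These counts argue against a chance assignment of the libraries to groups. Replicates may share 1 culture or transfection, so the splits cannot exclude chance differences between cultures.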

How the results depend on the processing

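The fits with counts divided by 4, with protein-coding genes only and without genes holding a motif, and the list tests with 1 library left out, were chosen after seeing the data. The counts of called genes for siRNA 1, siRNA 2, the mean of both, their difference and the shared genes stayed within 1.5 times the reported ones under other scaling, filters, tests and samples. With each library left out they ran from 5331 to 6368, 4699 to 5397, 5576 to 6400, 2695 to 3749 and 3031 to 3311. A 2-fold threshold in addition left 527, 312, 363, 189 and 129, since most changes were small. The balance of higher against lower calls depended on the processing. With scaling by library size only 2540 genes rose and 3068 fell for siRNA 2, in place of 2970 and 2627, and 3112 and 3510 for the mean of the siRNAs, in place of 3387 and 3208. Shared genes were 1700 higher and 1961 lower, in place of 1918 and 1761, and between the siRNAs 2017 were higher and 1666 lower under siRNA 1, in place of 1694 and 2058. For siRNA 1, in place of 3281 and 3108, 3198 genes rose and 3205 fell with library size only, 3200 and 3205 with DESeq2 size factors, 3182 and 3242 with only the groups compared, and 2662 and 2699 without siRNA 1 replicate 3. Shared genes were 1727 higher and 1748 lower with only the groups compared. With the 2-fold threshold 101 rose and 211 fell for siRNA 2 and 159 and 204 for the mean, and 141 were higher and 48 lower between the siRNAs. The ORM1 change under siRNA 2 missed the threshold by DESeq2's Wald test (−3.23, adjusted p = 0.072) and with no count filter (−3.2, 0.054), and ranged from −3.88 to −2.63 with 1 library left out. By limma-voom it was −4.04, that under siRNA 1 −5.78 and that of ORM2 in the mean of the siRNAs −3.55, in place of −3.2, −5.09 and −2.57. For siRNA 1 it ranged from −5.11 to −4.52 with 1 library left out, apart from the fit without siRNA 1 replicate 3, where both remaining siRNA 1 libraries are at 0 and no fold is given. The ORM2 change for the mean of the siRNAs missed the threshold with no count filter (−2.57, adjusted p = 0.073) and with the replicate block (−2.55, 0.057). With an estimated correlation 8 lists were called for siRNA 1 and 8 for siRNA 2, in place of 13 each, and fry, which does not compare a list with other genes, called 25, 25 and 27 for siRNA 1, siRNA 2 and their mean. Without genes holding a motif the cholesterol call for the mean was lost (adjusted p = 0.0852, median −0.107 in place of −0.203) and so was the ribosomal protein call for siRNA 1 (0.0553), while the ATF4 (0.0168) and housekeeping lists (0.0256) were called for siRNA 2. Beyond these constructions the cause was not tested. Under other scaling, the medians of some uncalled lists changed sign, namely housekeeping (siRNA 1 and mean), fatty acid oxidation (siRNA 2 and mean), glycolysis, ribosomal protein and unfolded protein response (siRNA 2) and mitochondrially encoded genes (mean). Of the values of named genes under alternatives, 9539 kept their direction and side of the threshold, 332 were no longer past it and 0 reversed. For called lists, under an estimated correlation, fry, the block and the test without motif genes, 198 values stayed past the threshold and 26 did not. List tests with 1 library left out are not in this count, and some calls were lost there too.

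The replicate numbers did not pair the libraries, since residuals of libraries with the same number correlated at −0.09 to 0.16, and those with different numbers at −0.25 to 0.31. With the replicate number as a block the counts were 6452, 5589, 6631, 3794 and 3726. Among lists the block ended the STAT3 call for the mean (adjusted p = 0.0503) and added ribosomal proteins for the mean (0.00395) and the difference (0.0393) and housekeeping genes for siRNA 2 (0.0153). The pseudocount alternative did not apply to counts, and a fit of only the groups compared exists for no mean of the siRNAs. At this depth 3 counts are 0.042 to 0.0494 CPM, more where a fragment was counted several times, so that falls of genes as low as ORM1 are measured with few counts.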

Other observations

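Further members of the gene lists changed under 1 siRNA or both. IRS1, an adaptor of insulin receptor signalling, changed from 65.0 ± 3.0 CPM to 112 ± 0.87 and 87.0 ± 2.8 CPM. PKP3, a desmosome protein, rose from 79.2 ± 2.2 CPM to 129 ± 0.62 and 102 ± 2.6 CPM. BCL2L11, which encodes the pro-apoptotic protein BIM, rose from 32.5 ± 2.2 to 54.7 ± 2.2 CPM, against 33.2 ± 2.0 CPM under siRNA 2. MT-RNR2, the mitochondrial large ribosomal RNA, rose from 5605 ± 209 to 7568 ± 129 CPM under siRNA 1 and was called lower under siRNA 2, at 5199 ± 178 CPM. The MT-RNR2 call under siRNA 2 was lost with no count filter and without siRNA 2 replicate 1 or control replicate 3. EDEM1, which directs misfolded glycoproteins to degradation, changed from 70.3 ± 2.5 CPM to 46.5 ± 2.0 and 50.8 ± 2.0 CPM. ATP5F1A, a subunit of ATP synthase in the list of oxidative phosphorylation, had 547 ± 6.8 CPM in control, 433 ± 4.3 CPM under siRNA 1 and 561 ± 18.9 CPM under siRNA 2, with a log2 difference between the siRNAs of −0.37 (SE 0.03). Under siRNA 2 SNAI2, a transcription factor of mesenchymal cells, fell from 0.961 ± 0.23 to 0.259 ± 0.088 CPM, against 1.53 ± 0.50 CPM under siRNA 1.

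Of the genes called in opposite directions, 6 more are given here, chosen after their values were seen. DIAPH3, a formin that nucleates actin, had 37.4 ± 2.3 CPM in control, 22.4 ± 2.0 CPM under siRNA 1 and 50.7 ± 1.7 CPM under siRNA 2. ME2, the mitochondrial malic enzyme, had 63.2 ± 0.87 CPM in control, 35.6 ± 1.6 CPM under siRNA 1 and 72.7 ± 1.6 CPM under siRNA 2. CDK8, a kinase of the Mediator complex, had 39.9 ± 2.0 CPM in control, 25.3 ± 1.6 CPM under siRNA 1 and 46.4 ± 2.5 CPM under siRNA 2, and ARRDC4, an arrestin-domain protein, 11 ± 1.1 CPM in control, 16.1 ± 0.62 CPM under siRNA 1 and 7.59 ± 0.59 CPM under siRNA 2. DUSP4, a phosphatase of MAP kinases, was higher under siRNA 1, with 213 ± 2.6 CPM in control, 324 ± 5.5 CPM under siRNA 1 and 192 ± 3.6 CPM under siRNA 2, and MCM6, a subunit of the replicative helicase in the G1/S list, was lower, with 144 ± 4.4 CPM in control, 122 ± 1.6 CPM under siRNA 1 and 194 ± 4.8 CPM under siRNA 2.

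The word TATTTAT, which resembles the AU-rich elements of short-lived mRNAs, had the lowest association score of all words under siRNA 2 against control, z = −6.7, against −4.9 in shuffled data. It is held by 4228 of the searched genes, whose median log2 change under siRNA 2 was −0.02, against 0.03 in genes without it. Across genes, which are not independent replicates, the log2 CPM of replicates correlated at Pearson r = 0.9831 to 0.9895. Counts of replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 9.01 to 13.67, a ratio that repeated counting of fragments would raise too.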
